A study of Homo sapiens with 19 samples.

How the data were processed

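Messenger RNA was profiled in immortalized human meibomian gland epithelial cells (IHMGECs), an established line from the eyelid gland that secretes the lipids of the tear film. The cells received lentivirus that carried GFP or KROX20, a zinc-finger transcription factor whose human gene is EGR2, and were taken 18, 42 or 66 h later, with 3 libraries for each virus and time. The labels call these biological replicates and place every library in batch 1, so no comparison between batches was possible. A single library came from uninfected cells, with no replicate and no stated time. Per the labels' protocols, virus was packaged in HEK 293 cells, a human embryonic kidney line, RNA was extracted with TRI Reagent, and libraries were made with a stranded poly(A) kit.

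Per the file headers, the deposited table of the whole series gave for each of 21532 genes a raw count, and the same libraries' RPKM, TPM and CPM values. The counts were whole numbers and were the values tested. The RPKM values, normalized by the authors to library size and gene length per the file headers, served only to recover the gene model length behind them, for 19896 genes. The deposited TPM and CPM values were not used. Tables for each time held the same 18 count columns, in which 0 cells differed, with the authors' own log2 fold changes and adjusted p-values, and these are quoted only where the authors' deposited table is named. No column of values matching no sample was found (0). The submitters' processing notes name GRCh38 as the genome build. The aligner, the counting tool, the gene annotation and whether counting used strand are not given in the sources used here. Genes that overlap, antisense pairs and genes with near-identical copies are therefore uncertain, and among those named here FRG2, FRG2B, FRG2C, RGPD6, HSPA1A, KRT6A and KRT6C have such copies. GC content was taken from GENCODE 29 for 21294 genes and used only to match genes in checks, and gene coordinates are those of the deposited table.

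Library totals ran from 21198550 to 29764351 counts. Floors cover counting error only, since reads amplified by PCR are not independent molecules. Intervals are binomial ones for shares of genes and treat genes as independent. Where the 3 control libraries held 0 counts of a gene, its fold is a lower bound against a floor of 3 counts over the group. For numbers of detected genes each library was also thinned at random to 20000000 counts.

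Counts were tested with edgeR 4.0.16 in R 4.3.3. The 18 infected libraries entered one quasi-likelihood fit with a mean for each of 6 groups, TMM normalization and the filterByExpr filter, which left 15453 genes. Contrasts were Krox20 against GFP at each time, the difference of that effect between times (an F test over the 3 times, and 66 h against 18 h), and GFP at 42 or 66 h against 18 h. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided, and every adjusted p of a gene printed here comes from this edgeR fit unless another source is named. Levels are TMM-scaled CPM (counts scaled to a common library total), as mean ± SD over 3 libraries, except that EGR2 levels per library and all levels of switched-on genes are plain CPM. Fold changes are log2 values ± SE.

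The named genes were chosen by rule. For each Krox20 comparison and for GFP at 66 against 18 h these were EGR2, NOTCH1, the 6 genes with the highest and the 6 with the lowest fold change among called genes of average log2 CPM of at least 3 whose libraries did not overlap between groups, the called members of the Notch and EGR/NAB lists, and up to 4 members of each other list with the smallest adjusted p. The 5 genes with the smallest adjusted p were added for the difference between times, and up to 4 members of each list by size of fold for the uninfected library. There were 22 gene lists, written from general knowledge: Notch signalling, EGR and NAB genes, myelin genes, meibocyte lipid genes, cholesterol synthesis, basal and stem cell markers, keratinocyte differentiation, cell cycle, p53 targets, interferon response, NF-kB target cytokines, AP-1 and early response genes, the unfolded protein and stress response, mesenchymal and matrix genes, Wnt and hedgehog genes, ribosomal proteins, mitochondrially encoded genes, nuclear genes of oxidative phosphorylation, and markers of fibroblasts, endothelial and immune cells, melanocytes and HEK 293 cells. For each list the members called over all genes are counted by direction, with the number called when adjusted over the list alone. Camera in limma 3.58.1 tested each list against all other genes with a preset correlation of 0.01, two-sided and adjusted over 63 tests (21 lists at 3 times), and again with an estimated correlation. The melanocyte list had 2 tested members and no camera test. Groups, designs, lists, the naming rule and all alternatives but 2 were fixed before the data were examined.

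The uninfected library was compared with the mean of the GFP 18 h libraries without a test, over genes of at least 8 CPM in mean, with a pseudocount of 0.5 CPM. The median of each list was placed among 10000 random lists matched on expression.

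The gene and list tests were tried on simulated counts with known changes. For a simulated comparison at 18 h with 14516 genes tested, edgeR recovered 38.8% of genes changed 1.5-fold, 71.6% of those changed 2-fold and 98.5% of those changed 4-fold, with 8 false calls. Limma-voom made 6 and DESeq2 54. The list test on 14500 simulated genes recovered 1 of 1 shifted lists and called 0 of the others. Simulated genes were drawn independently, without correlation between genes or a trend with gene length. These numbers therefore check the code and do not measure the error rate in the real libraries. Replicate pairs differed beyond sampling noise in each group, with chi-square per degree of freedom from 1.56 to 226, so no library was treated as a copy of another. That spread cannot tell whether the libraries of a group came from separate cultures or infections.

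Alternatives were DESeq2 size factors and library size alone in place of TMM, no filter and a mean of at least 10 counts, DESeq2 1.42.0 and limma-voom as tools, EGR2 left out of the counts, replicate numbers as a block, each library left out in turn, an adjusted p under 0.01, and at least a 2-fold change. Fits without 4 libraries whose trend with gene length stood apart, and fits on the 6 libraries of a time alone, were compared as well; the former was added after the data were seen, as was the list test with no filter, over every list member with a count (66 tests). Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.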

Results

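Messenger RNA was sequenced from immortalized human meibomian gland epithelial cells 18, 42 and 66 h after infection with a lentivirus that carried GFP or KROX20, and from 1 culture without virus. The series title places KROX20 and NOTCH1 in one network of meibomian gland stem cells. Each Krox20 group was set against GFP cells of the same age. There were 18 infected libraries in 6 groups of 3, and 1 uninfected library. Library totals ran from 21198550 counts, in Krox20 66 h replicate 2, to 29764351, in Krox20 18 h replicate 2.

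EGR2, the human KROX20 gene (ENSG00000122877, GRCh38 chromosome 10, 62811996 to 62819167), separated the groups as labelled. It had 9, 14 and 71 counts in the GFP 18 h libraries and 41264, 13215 and 43770 in the Krox20 18 h libraries, or 1.13 ± 1.26 against 1126 ± 592 CPM (SD, n = 3). At 42 h the mean was 0.477 ± 0.116 CPM with GFP and 4675 ± 206 with Krox20. At 66 h it was 0.880 ± 0.228 and 5744 ± 516. The uninfected library held 75 counts, 2.54 CPM. Log2 fold changes over GFP were 10.05 ± 0.64, 12.95 ± 0.72 and 12.39 ± 0.69 (SE), with edgeR adjusted p of 7.6e-09, 4.8e-10 and 3.4e-10. At 18 h the log2 fold change of EGR2 was 11.52 without GFP replicate 3. In Krox20 replicate 2 of that time EGR2 was at 444 CPM, below the other two (1427 and 1508). Whether the carried KROX20 sequence was human, or held the untranslated regions, is not given in the sources used here, so these counts cannot separate viral from endogenous EGR2.

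**Figure D1:**
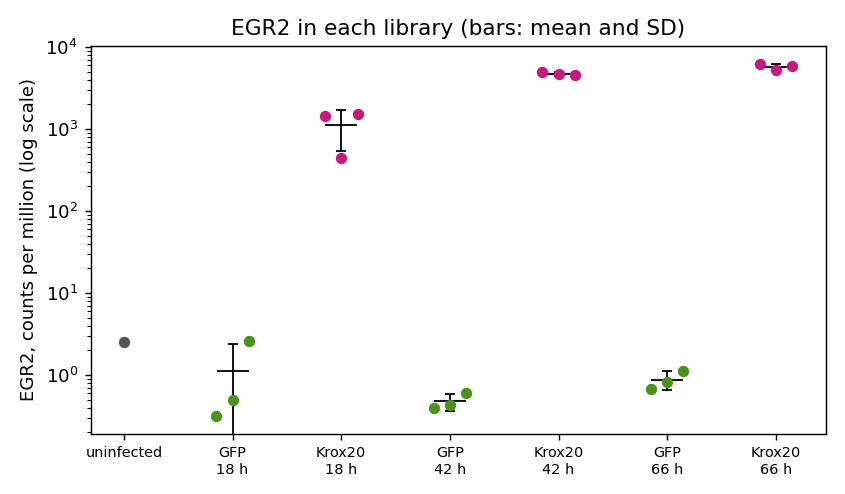
EGR2 in CPM on a log scale in each of the 19 libraries, by group, with points for libraries and bars for the mean and SD of 3. Krox20 libraries lie between 444 and 6150 CPM, and all other libraries between 0.315 and 2.59 CPM.

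At 18 h the genes with the highest folds in Krox20 cells included NES, which encodes the intermediate filament nestin. NES went from 0.404 ± 0.296 to 391 ± 9.81 CPM (SD, n = 3), a log2 fold change of 9.93 ± 0.28 (SE). METTL7B (10.55 ± 0.31) and the cystatin gene CST6 (9.35 ± 0.38) were higher too. GRM4, a glutamate receptor gene, and NRXN2, a neurexin gene, had 0 counts in the GFP libraries and were at least 113.4-fold and at least 70.16-fold higher. The lowest folds were those of the chemokine genes CXCL8 (-4.38 ± 0.17), CXCL2 (-4.33 ± 0.22) and CXCL3 (-3.52 ± 0.13), the Wnt inhibitor gene DKK1 (-4.00 ± 0.09), COQ8A (-3.58 ± 0.29) and FGFBP1 (-3.41 ± 0.17). DKK1 went from 223 ± 9.35 to 13.9 ± 1.21 CPM. The largest edgeR adjusted p among the genes of this paragraph was 1.3e-07, for COQ8A.

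Sterol synthesis and cell cycle genes were lower at 18 h, and genes of the unfolded protein response were higher. Of 24 cholesterol synthesis genes, 21 fell and 0 rose (22 called when adjusted over the list alone), among them LSS (-1.49 ± 0.09), DHCR7 (-1.22 ± 0.09) and IDI1 (-0.89 ± 0.06). Of 45 cell cycle genes, 30 fell and 3 rose (34 over the list alone). The mitotic genes AURKA (-1.13 ± 0.06), CCNB1 (-1.30 ± 0.09) and NUSAP1 (-1.56 ± 0.11) were examples. Of 28 stress response genes, 19 rose and 2 fell (24 over the list alone). The chaperone gene HSPA5 went from 497 ± 19.3 to 2934 ± 116 CPM (2.56 ± 0.07), HERPUD1 rose by 2.66 ± 0.06 and PDIA4 by 1.77 ± 0.08, while DDIT4 changed by -1.67 ± 0.06. Camera adjusted p was 4.1e-11 for cholesterol synthesis, 4.7e-09 for the cell cycle and 3.7e-08 for the stress response. These calls held with an estimated correlation (adjusted p = 0.0011, 0.013 and 0.013).

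Inflammatory genes fell and matrix genes rose at that time. Of 29 NF-kB cytokine genes, 18 fell and 6 rose (24 over the list alone), with camera adjusted p = 8.3e-06 and adjusted p = 0.013 with an estimated correlation. ICAM1, an adhesion molecule (4.27 ± 0.13), and LIF, a cytokine (4.18 ± 0.13), went against the list and rose. Of 41 interferon response genes, 18 fell and 1 rose (20 over the list alone), with IFIT1 at -1.47 ± 0.09 and MX1 at -1.06 ± 0.10. Camera adjusted p for this list was 4.4e-05, and adjusted p = 0.035 with an estimated correlation. Of 31 mesenchymal and matrix genes, 20 rose and 3 fell (25 over the list alone), such as TGFBI (2.25 ± 0.07) and MMP2 (1.25 ± 0.07). Its camera adjusted p was 0.00084, and adjusted p = 0.36 with an estimated correlation.

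Of 9 tested fibroblast markers (12 listed), 5 rose and 0 fell at 18 h (6 over the list alone), with the collagen genes COL1A1 at 2.53 ± 0.10 and COL6A3 at 4.42 ± 0.40. Its camera adjusted p of 0.015 became adjusted p = 0.065 with an estimated correlation. Of 7 tested genes of the HEK 293 list (14 listed), 3 rose and 0 fell (3 over the list alone, camera adjusted p = 0.081), and the neurofilament gene NEFM rose by 4.80 ± 0.17. Genes near 0 with GFP pass the count filter only if Krox20 raises them, so in lists of such genes the share that rose and the camera p favour a rise. With no filter, an alternative added after seeing the data, 6 of 12 fibroblast markers rose and 0 fell at 18 h (camera adjusted p = 0.0068, and 0.038 with an estimated correlation), and 4 of 14 HEK 293 markers rose and 0 fell (0.062 and 0.19). In total 5338 of 15453 genes were called at 18 h, 2922 higher and 2416 lower, and 1743 of them (1309 and 434) were at least 2-fold apart. Scaling to library size alone turned the share of higher calls from 54.7% to 40.6%. In 4 libraries (GFP 18 h replicate 3, Krox20 18 h replicate 2, GFP 42 h replicate 3 and GFP 66 h replicate 1) the rank correlation of level and gene length lay 0.085 or more below the mean of the other two libraries of the group. Without these 4 libraries, an alternative added after seeing the data, 8253 genes were called at 18 h, and fibroblast markers had camera adjusted p = 0.11.

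At 42 h several genes with 0 counts in the GFP libraries were abundant with Krox20. CPNE6 reached 78.4 ± 2.70 CPM (SD, n = 3), at least 1970-fold higher. NRXN2 was at least 1883-fold, METTL7B at least 1238-fold and FRG2B at least 955.5-fold higher. FRG2B has near-identical copies and is uncertain. NPR1, a natriuretic peptide receptor gene, rose by 13.49 ± 0.32 (SE). The lowest folds were those of the protease inhibitor genes SERPINB1 (-3.54 ± 0.13) and SERPINB2 (-2.91 ± 0.12), ALDH3A1 (-3.32 ± 0.16), HS3ST1 (-3.17 ± 0.10), A2ML1 (-2.999 ± 0.28) and the keratin gene KRT6C (-2.91 ± 0.19), which has close copies and is uncertain. The largest edgeR adjusted p of the genes of this paragraph was 1.8e-07, for A2ML1.

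The stress response list was lower at 42 h, with 20 of 28 genes fallen and 3 risen (24 over the list alone), TRIB3 at -2.03 ± 0.09, DDIT4 at -1.88 ± 0.06 and XBP1 at -1.16 ± 0.07. Its camera adjusted p was 2.0e-05, and adjusted p = 0.041 with an estimated correlation. Ribosomal protein genes fell in 23 of 37 cases and rose in 0 (23 over the list alone), among them RPL4 (-0.96 ± 0.17) and RPL15 (-0.94 ± 0.14). Their camera adjusted p was 0.00033, and adjusted p = 0.72 with an estimated correlation. Rank correlations of level and gene length ran from 0.006 to 0.035 in Krox20 42 h libraries and from -0.154 to -0.063 in GFP 42 h libraries. The interleukin gene IL1B fell (-2.82 ± 0.06) with 18 of the 29 NF-kB cytokine genes in all, while 8 rose, ICAM1 by 8.12 ± 0.14 and TNFAIP2 by 7.09 ± 0.26 (26 over the list alone). Camera gave that list adjusted p = 0.014, and adjusted p = 0.10 with an estimated correlation. AP-1 and early response genes fell in 18 of 32 cases and rose in 9 (27 over the list alone), FOSL1 at -2.54 ± 0.09 and FOSB at 4.69 ± 0.11, with camera adjusted p = 0.033, and adjusted p = 0.32 with an estimated correlation.

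Interferon genes fell in 18 of 41 cases and rose in 5 at 42 h (23 over the list alone), with OAS1 at -1.85 ± 0.13. Camera adjusted p for interferon genes was 0.030, with adjusted p = 0.22 with an estimated correlation and 0.056 without the 4 libraries named above. Of the cholesterol genes 13 fell and 4 rose (18 over the list alone), SQLE at -1.17 ± 0.11 and MSMO1 at 0.58 ± 0.07. Camera gave cholesterol genes adjusted p = 0.046, adjusted p = 0.15 with an estimated correlation, 0.055 with DESeq2 size factors and 0.11 with library size alone. Of 45 cell cycle genes 25 rose and 5 fell (30 over the list alone), with CDC6 at 2.07 ± 0.08. Their camera adjusted p was 0.081, but 0.026 with library size alone and 0.031 without the 4 libraries. Mesenchymal and matrix genes rose in 10 of 31 cases and fell in 15 (25 over the list alone), PLAU at -2.08 ± 0.06 and SNAI1 at 5.07 ± 0.28, with camera adjusted p = 0.070 and 0.027 with library size alone.

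Fibroblast markers rose in 7 of 9 cases and fell in 1 at 42 h (8 over the list alone), with COL1A1 at 4.68 ± 0.11. Camera gave them adjusted p = 0.015, adjusted p = 0.065 with an estimated correlation and 0.090 without the 4 libraries. HEK 293 markers rose in 5 of 7 cases and fell in 1 (6 over the list alone), with NEFM at 6.97 ± 0.20. The filtered camera call of HEK 293 markers (adjusted p = 0.045) is not relied on, as with no filter 6 of 14 rose and 2 fell with adjusted p = 0.21, and the call also ended in each other alternative. With no filter 7 of 12 fibroblast markers rose and 1 fell (camera adjusted p = 0.025, and 0.077 with an estimated correlation). In total 10880 genes were called at 42 h, 6286 higher and 4594 lower, and 5773 (4176 and 1597) were at least 2-fold apart. Scaling to library size alone moved the share of higher calls from 57.8% to 71.7%. It moved the median log2 fold change of all tested genes from 0.161 to 0.457 at 42 h, from 0.015 to 0.288 at 66 h and from 0.033 to -0.065 at 18 h. Interferon genes, with a median of -0.28 at 42 h and 0.02 with library size alone, stayed below that median of all genes.

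At 66 h CPNE6 (175 ± 4.42 CPM, SD, n = 3), FRG2B, the prostaglandin synthase gene PTGDS and GRM4 had 0 counts in GFP libraries. They were at least 4695-fold, at least 3537-fold, at least 3179-fold and at least 1498-fold higher with Krox20. ELN, the elastin gene, went from 0.0127 ± 0.0219 to 230 ± 13.0 CPM, a log2 fold change of 13.72 ± 0.31 (SE), and NPR1 rose by 13.42 ± 0.32. The lowest folds belonged to the interferon gene IFI44L (-4.75 ± 0.19), CLMN (-3.61 ± 0.21), SERPINB1 (-3.55 ± 0.13), AKR1C1 (-3.42 ± 0.17), the collagenase gene MMP1 (-3.31 ± 0.18) and ADAM8 (-3.30 ± 0.09). The largest edgeR adjusted p of these 12 genes was 6.5e-09, for FRG2B.

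Interferon response genes fell in 36 of 41 cases and rose in 0 at 66 h (37 over the list alone). IFI44L was at 42.6 ± 2.34 CPM with GFP and 1.58 ± 0.114 with Krox20, MX1 had a log2 fold change of -2.70 ± 0.10 and OAS1 of -2.55 ± 0.13. Cholesterol synthesis genes fell in 21 of 24 cases and rose in 0 (21 over the list alone), SQLE at -1.70 ± 0.11 and INSIG1 at -1.25 ± 0.05. Camera adjusted p was 8.6e-07 and 6.5e-06, and both calls held with an estimated correlation (adjusted p = 0.013 and 0.013). Cell cycle genes rose in 30 of 45 cases and fell in 5 (35 over the list alone), CDC6 at 3.84 ± 0.09 and CCNB1 at 2.36 ± 0.10. Their camera adjusted p was 0.0016, and adjusted p = 0.15 with an estimated correlation. Stress response genes fell in 21 of 28 cases and rose in 3 (25 over the list alone), TRIB3 at -3.12 ± 0.10 and ATF4 at -2.31 ± 0.15. Their camera adjusted p was 0.00084, and adjusted p = 0.10 with an estimated correlation.

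Ribosomal protein genes fell in 35 of 37 cases and rose in 0 at 66 h (35 over the list alone), with RPL5 at -1.60 ± 0.20. Camera gave them adjusted p = 6.2e-05, and adjusted p = 0.72 with an estimated correlation, and their median of -1.09 was -0.67 without the 4 libraries. Of 13 mitochondrially encoded genes 10 rose and 0 fell (10 over the list alone), MT-ND1 by 1.32 ± 0.09 and MT-CYB by 1.08 ± 0.07. Camera gave them adjusted p = 0.015, and adjusted p = 0.28 with an estimated correlation. Mitochondrially encoded genes took 8.74 ± 0.376% of the counts in Krox20 66 h libraries (SD, n = 3) and 4.73 ± 0.222% in GFP 66 h libraries. Fibroblast markers rose in 8 of 9 cases and fell in 1 (9 over the list alone), COL6A3 by 9.72 ± 0.44 and PDGFRB by 9.11 ± 0.39. HEK 293 markers rose in 6 of 7 tested cases and fell in 0 (6 over the list alone), NEFM by 8.27 ± 0.20. Filtered camera adjusted p was 0.0036 and 0.0036, and 0.035 and 0.035 with an estimated correlation. With no filter 9 of 12 fibroblast markers rose and 1 fell (camera adjusted p = 0.0071, and 0.038 with an estimated correlation). With no filter 8 of 14 HEK 293 markers rose and 0 fell (camera adjusted p = 0.019), but that call ended with an estimated correlation (0.097). In total 11341 genes were called at 66 h, 5902 higher and 5439 lower, and 6539 (4180 and 2359) were at least 2-fold apart. Scaling to library size alone moved the share of higher calls from 52% to 64%.

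**Figure D2:**
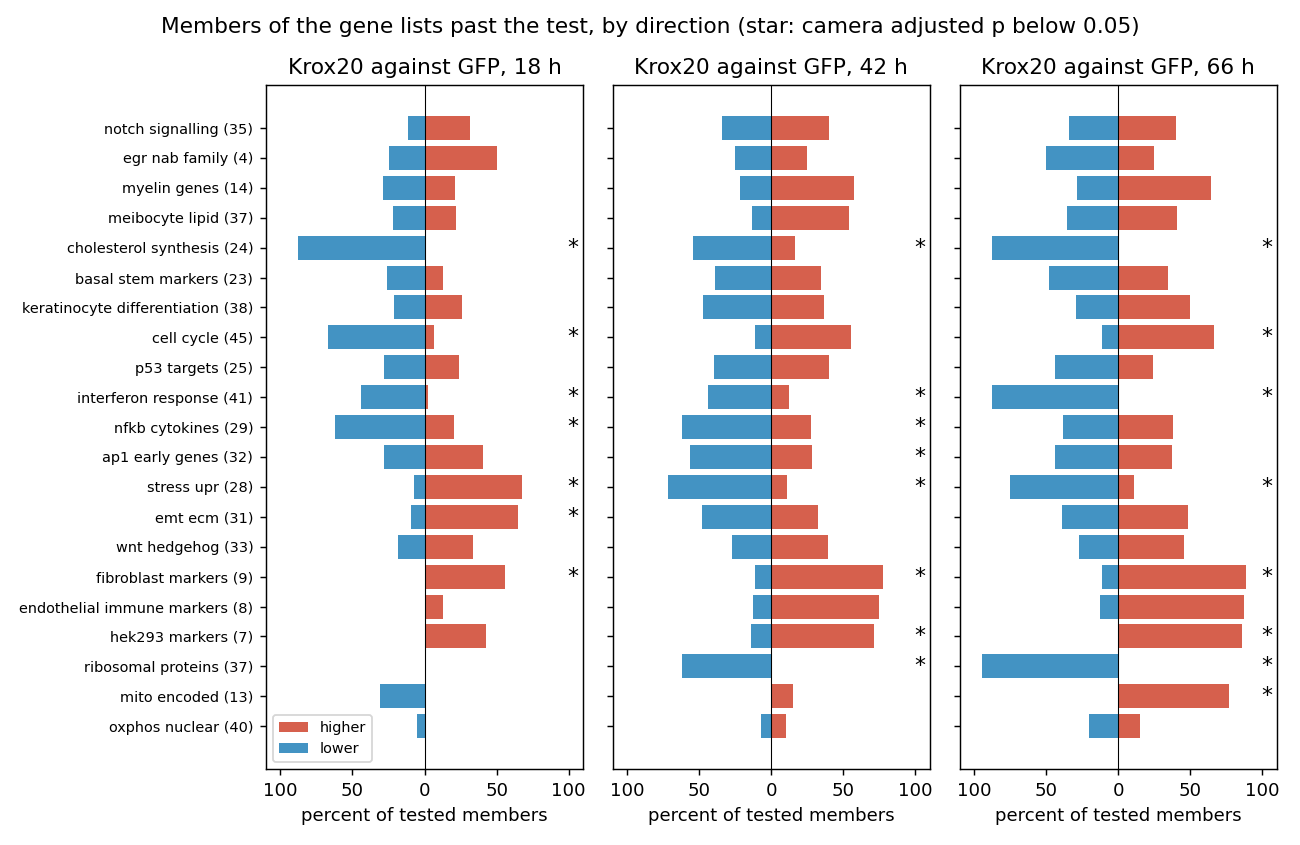
Percent of tested members of each gene list called higher (red) or lower (blue) in Krox20 than in GFP libraries at each time, with stars for camera adjusted p under 0.05; lists of genes near 0 with GFP are biased upward by the count filter. Cell cycle genes change from 30 of 45 lower at 18 h to 30 higher at 66 h.

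Notch pathway genes moved in both directions at each time. NOTCH1 (ENSG00000148400, chromosome 9, 136494433 to 136546048) was at 454 ± 77.1 and 264 ± 90.0 CPM with GFP and Krox20 at 18 h (SD, n = 3), and at 514 ± 97.4 and 269 ± 14.1 at 42 h. Its log2 fold changes of -0.78 ± 0.28, -0.93 ± 0.28 and -1.38 ± 0.28 (SE) had edgeR adjusted p of 0.039, 0.0071 and 0.00036, and the differences between times did not pass the test (adjusted p = 0.37). NOTCH3 (ENSG00000074181, chromosome 19, 15159038 to 15200995) rose by 3.12 ± 0.35, 3.50 ± 0.33 and 3.51 ± 0.33, and NOTCH4 by 4.94 ± 0.44, 8.20 ± 0.38 and 8.45 ± 0.39. LFNG, which encodes a glycosyltransferase acting on Notch receptors, went from 0.425 ± 0.323 to 84.4 ± 1.33 CPM at 66 h. The target gene HEYL rose by 5.28 ± 0.49, 6.73 ± 0.49 and 6.30 ± 0.41 at the 3 times and HES4 by 5.27 ± 0.36, 3.45 ± 0.29 and 1.75 ± 0.27. HES2 changed by -0.81 ± 0.05, -1.43 ± 0.05 and -1.41 ± 0.05. Among ligand genes, DLL4 rose by 2.25 ± 0.57, 9.37 ± 0.39 and 7.24 ± 0.32, JAG2 changed by -1.48 ± 0.11 at 66 h, and JAG1 by -0.82 ± 0.25 at 42 h.

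Of 35 tested Notch genes, 11 rose and 4 fell at 18 h, 14 rose and 12 fell at 42 h, and 14 rose and 12 fell at 66 h (16, 26 and 26 called over the list alone). Camera gave adjusted p of 0.14, 0.96 and 0.96, and 0.049 at 18 h without the 4 libraries that followed gene length differently. The NOTCH1 call at 18 h was lost without GFP replicate 1, GFP replicate 2 or Krox20 replicate 2 of that time, and in 3 more of 17 alternatives. There NOTCH1 had adjusted p up to 0.13, and its log2 fold changes over all 17 ran from -0.93 to -0.49. With library size alone NOTCH1 (-0.64, adjusted p = 0.069) and JAG1 (-0.53, adjusted p = 0.10) no longer passed at 42 h. In the authors' deposited table NOTCH1 had log2 fold changes of -0.66, -1.07 and -1.46.

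**Figure D3:**
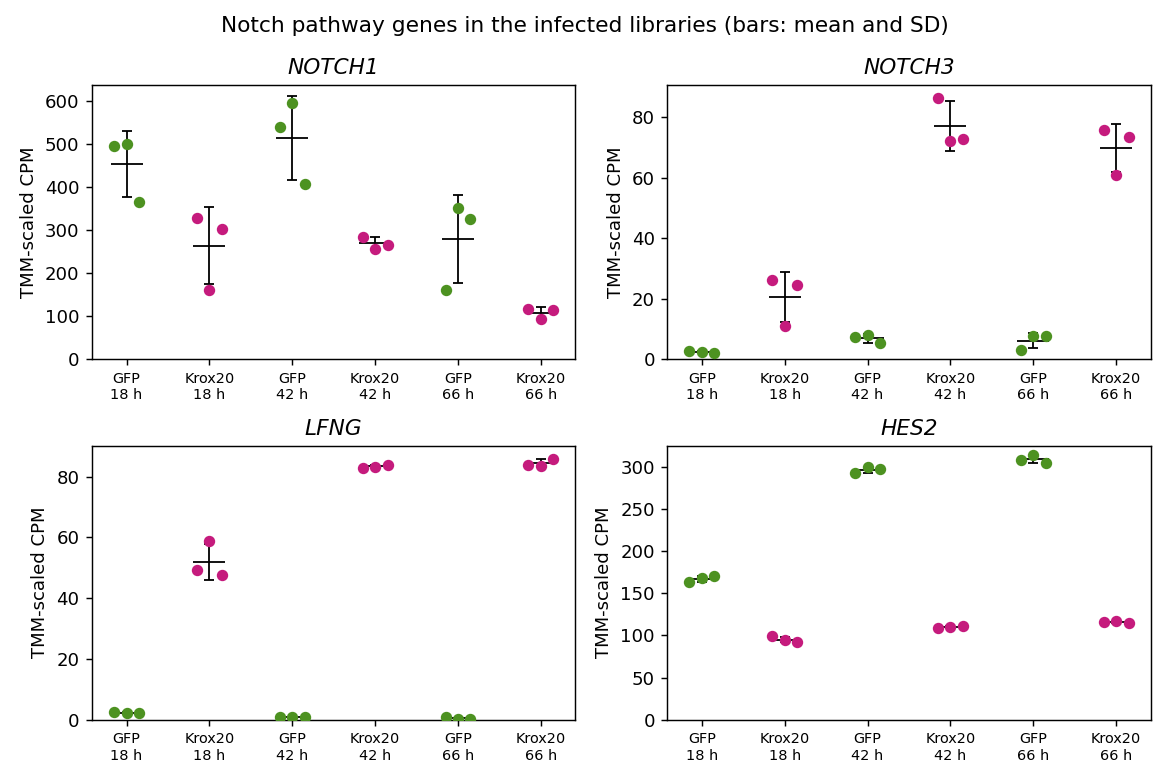
TMM-scaled CPM of NOTCH1, NOTCH3, LFNG and HES2 in each infected library, by group, with bars for the mean and SD of 3. NOTCH1 and HES2 means are lower with Krox20 at each time, and those of NOTCH3 and LFNG are higher.

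Other EGR genes changed as well. EGR3 rose by 5.23 ± 0.30, 5.36 ± 0.30 and 4.94 ± 0.29 at the 3 times, and EGR1 changed by -1.89 ± 0.10, -2.22 ± 0.10 and -3.11 ± 0.10. NAB2, which encodes a corepressor of EGR proteins, rose by 0.86 ± 0.08 at 18 h, and NAB1 changed by -0.67 ± 0.23 at 66 h. The NAB1 call was lost with library size alone and in a fit to the 6 libraries of that time. Of 4 tested genes of this list other than EGR2, 2 rose and 1 fell at 18 h, 1 rose and 1 fell at 42 h, and 1 rose and 2 fell at 66 h (3, 2 and 3 over the list alone, camera adjusted p = 0.62, 0.93 and 0.80). Of 14 myelin genes, targets of KROX20 in Schwann cells among them, 3 rose and 4 fell, 8 rose and 3 fell, and 9 rose and 4 fell (8, 11 and 13 over the list alone, camera adjusted p = 0.93, 0.50 and 0.39). POU3F1 rose by 2.61 ± 0.11, 2.16 ± 0.11 and 2.68 ± 0.11, PRX by 1.09 ± 0.08 and 1.26 ± 0.08 at 18 and 42 h, and PLLP changed by -1.36 ± 0.18, -1.90 ± 0.18 and -3.05 ± 0.19.

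Lipid genes of meibocytes, the secretory cells of the gland, did not pass as a list. ELOVL3, a fatty acid elongase gene, rose by 3.59 ± 0.10 at 42 h and by 5.50 ± 0.11 at 66 h, from 1.19 ± 0.157 to 53.8 ± 0.645 CPM (SD, n = 3). CYP4F2 rose by 5.75 ± 0.29 and MLXIPL by 5.63 ± 0.33 at 42 h, and at 18 h DGAT2 rose by 1.38 ± 0.10 and ELOVL6 changed by -1.29 ± 0.12. Of 37 lipid genes 8 rose and 8 fell, 20 rose and 5 fell, and 15 rose and 13 fell at the 3 times (20, 25 and 28 over the list alone, camera adjusted p = 0.54, 0.081 and 0.54). SBSN, a suprabasal epidermal gene, rose from 5.13 ± 1.38 to 4798 ± 66.3 CPM at 66 h, the kallikrein gene KLK7 by 7.16 ± 0.11 and the filaggrin gene FLG by 7.98 ± 0.32, while KRT6A, uncertain for its close copies, changed by -1.93 ± 0.08 at 42 h. Of 38 keratinocyte differentiation genes 10 rose and 8 fell, 14 rose and 18 fell, and 19 rose and 11 fell (19, 32 and 30 over the list alone, camera adjusted p = 0.53, 0.50 and 0.33). Their 42 h median of -0.48 and mean of 0.53 differed in sign.

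Among 23 basal and stem cell markers, the keratin gene KRT15 changed by -1.92 ± 0.17, -2.45 ± 0.17 and -3.28 ± 0.18 and KRT5 by -0.80 ± 0.07, -1.56 ± 0.07 and -1.47 ± 0.07. KRT17 rose by 2.05 ± 0.22 at 18 h, and the hedgehog effector gene GLI1 rose by 2.62 ± 0.19, 2.83 ± 0.19 and 2.97 ± 0.21. In that list 3 rose and 6 fell, 8 rose and 9 fell, and 8 rose and 11 fell (9, 17 and 21 over the list alone, camera adjusted p = 0.39, 0.51 and 0.50). Of 33 Wnt and hedgehog genes 11 rose and 6 fell, 13 rose and 9 fell, and 15 rose and 9 fell (20, 22 and 24 over the list alone, camera adjusted p = 0.50, 0.91 and 0.50). Of 25 p53 targets 6 rose and 7 fell, 10 rose and 10 fell, and 6 rose and 11 fell (13, 20 and 17 over the list alone, camera adjusted p = 0.23, 0.88 and 0.51). The p53 target GDF15 rose by 1.76 ± 0.16, 3.29 ± 0.15 and 4.11 ± 0.16.

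Of 32 AP-1 and early genes 13 rose and 9 fell at 18 h and 12 rose and 14 fell at 66 h (23 and 26 over the list alone, camera adjusted p = 0.51 and 0.44), and the growth regulator gene MYC changed by -2.09 ± 0.06 and -2.48 ± 0.06. At 66 h 11 of 29 NF-kB cytokine genes rose and 11 fell (22 over the list alone, camera adjusted p = 0.93), CCL20 by 3.44 ± 0.16. Then 15 of 31 mesenchymal and matrix genes rose and 12 fell (27 over the list alone, camera adjusted p = 0.96). Of 8 tested endothelial and immune markers (14 listed) 1 rose and 0 fell at 18 h, 6 rose and 1 fell at 42 h, and 7 rose and 1 fell at 66 h (1, 7 and 8 over the list alone, camera adjusted p = 0.51, 0.26 and 0.18). The endothelial receptor gene TEK rose by 3.82 ± 0.41 and 7.07 ± 0.39, whereas CD68 changed by -1.66 ± 0.07 at 66 h. Of the 2 tested melanocyte markers (8 listed) 0 rose at 18 h and 2 at each later time (0, 2 and 2 over the list alone), PMEL by 2.73 ± 0.16 and 3.88 ± 0.17.

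Of 37 ribosomal protein genes 0 rose and 0 fell at 18 h (0 over the list alone, camera adjusted p = 0.93, and 0.0096 without the 4 libraries). Of 13 mitochondrially encoded genes 0 rose and 4 fell at 18 h and 2 rose and 0 fell at 42 h (3 and 1 over the list alone, camera adjusted p = 0.26 and 0.80). The 4 lower genes, MT-ND4 (-0.30 ± 0.09), MT-ND2, MT-CO1 and MT-ND6, each lost the call in 3 to 9 of 17 alternatives. Of 40 nuclear genes of oxidative phosphorylation 0 rose and 2 fell, 4 rose and 3 fell, and 6 rose and 8 fell (1, 7 and 9 over the list alone, camera adjusted p = 0.88, 0.28 and 0.50). At 66 h their median of -0.20 was 0.23 without the 4 libraries, and the direction of camera turned upward (adjusted p = 0.089), so no direction is stated. SDHA, a subunit of complex II, changed by -0.42 ± 0.06 and -0.59 ± 0.06 at 42 and 66 h.

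The Krox20 effect differed between times for 9417 of 15453 genes (F test over the 3 times, edgeR adjusted p under 0.05). Between 18 and 66 h it differed for 8028, 3562 with a higher and 4466 with a lower log2 fold at 66 h. The 5 genes with the smallest adjusted p were the histone gene H2BC21 (-0.52 ± 0.11, 5.00 ± 0.11 and 6.54 ± 0.12 at the 3 times), HERPUD1 (2.66, -0.9962 and -0.59), the heat shock gene HSPA1A (0.18 ± 0.07, 2.91 ± 0.08 and 4.80 ± 0.08), which has a near-identical copy and is uncertain, BCAM (0.08 ± 0.09, 4.76 ± 0.11 and 5.35 ± 0.11) and the mitotic kinase gene NEK2 (-1.14 ± 0.08, 2.27 ± 0.08 and 3.36 ± 0.08). Library size alone moved the share of genes with a higher fold at 66 h from 44.4% to 67.3%. Calls in the same direction at all 3 times were made for 1552 higher and 1279 lower genes. Between 42 and 66 h, 4776 higher and 3742 lower calls were shared, where independent lists would share 2401 and 1617. Between 18 and 42 h 1873 and 1468 were shared (1189 and 718 for independent lists), and between 18 and 66 h 1745 and 1502 (1116 and 850). Folds correlated across genes with Pearson r of 0.904, 0.561 and 0.51 in these pairs, where genes are not independent replicates.

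GFP cells changed with time, which set the level against which Krox20 was read. From 18 to 66 h, 39 of 45 cell cycle genes fell and 0 rose in GFP cells (39 over the list alone), with AURKA going from 77.5 ± 1.64 to 9.17 ± 0.633 CPM (SD, n = 3), CDC20 changing by -3.91 ± 0.11 (SE) and RRM2 by -3.81 ± 0.09. In Krox20 cells AURKA was at 35.4 ± 0.473 and 26.6 ± 0.377 CPM at those times. Of 41 interferon genes 37 rose and 0 fell (37 over the list alone), IFI44L by 5.79 ± 0.21, XAF1 by 4.29 ± 0.14 and MX1 by 2.31 ± 0.10. Other genes with the highest folds were SERPINA3 (6.32 ± 0.21), CYP1B1 (5.68 ± 0.29), ALDH3B2 (5.40 ± 0.10), GPNMB (5.35 ± 0.13) and RGPD6 (5.08 ± 0.46), which has near-identical copies and is uncertain. The lowest were those of the actin gene ACTC1 (-10.77 ± 2.45), MYBL2 (-5.06 ± 0.14), GTSE1 (-5.05 ± 0.18), KIF20A (-4.62 ± 0.19), CYP24A1 (-4.49 ± 0.24) and KIF18B (-4.49 ± 0.19). The largest edgeR adjusted p of these 12 genes was 0.0014, for ACTC1. Within the GFP 42 h libraries ACTC1 ran from 0.036 to 40.7 plain CPM, so its fall cannot be credited to time alone.

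Of 31 mesenchymal and matrix genes 23 fell and 1 rose in GFP cells over this time (24 over the list alone), MMP9 at -3.55 ± 0.11 and SPARC at -2.16 ± 0.06. Of 29 NF-kB cytokine genes 20 fell and 5 rose (25 over the list alone), CXCL8 at -3.22 ± 0.16. Of 28 stress genes 18 rose and 4 fell (22 over the list alone), DNAJB9 at 3.31 ± 0.10. In the Notch list 12 rose and 12 fell (25 over the list alone), with HEY1 at 3.17 ± 0.11, RBPJ at 1.96 ± 0.10, DLL1 at -3.48 ± 0.18 and JAG1 at -1.51 ± 0.26. NOTCH1 was at -0.70 ± 0.28 (edgeR adjusted p = 0.041), a call lost in 7 of 15 alternatives, with NOTCH1 adjusted p up to 0.25 and folds from -0.84 to -0.34. In total 8658 genes differed between 66 and 18 h, 4538 higher and 4120 lower, and 4380 between 42 and 18 h, 2274 higher and 2106 lower. Without the 4 libraries the latter number was 7675. Library size alone moved the share of higher calls at 66 h from 52.4% to 64.6%.

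**Figure D4:**
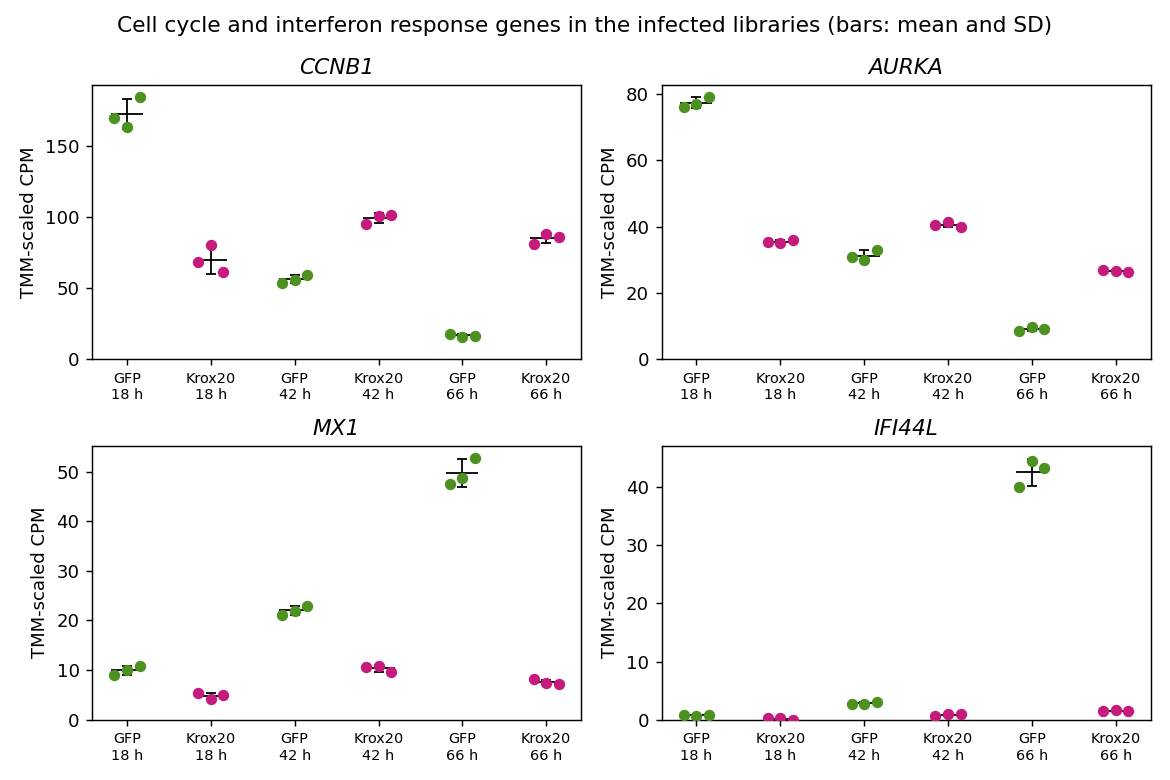
TMM-scaled CPM of the cell cycle genes CCNB1 and AURKA and the interferon genes MX1 and IFI44L in each infected library, by group, with bars for the mean and SD of 3. AURKA falls from a mean of 77.5 to 9.17 with GFP and lies at 35.4 and 26.6 with Krox20, at 18 and 66 h, and MX1 at 66 h is at 49.7 with GFP and 7.63 with Krox20.

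The uninfected library, without replicate and therefore without a test, was set beside the GFP 18 h libraries. Inflammatory and matrix genes were lower in uninfected cells, the gelatinase gene MMP9 44.8-fold, IL24 32.3-fold, PTGS2 31.0-fold, CXCL8 27.8-fold, CXCL1 19.4-fold, ATF3 10.5-fold, THBS1 8.51-fold and FN1 7.82-fold. NOTCH1 was 2.50-fold lower (179.9 against 450.1 ± 76.5 CPM, SD, n = 3) and JAG1 2.54-fold lower. The differentiation genes SPRR3 and KRT13 were 7.74-fold and 7.52-fold higher, the chaperone gene HSP90B1 6.77-fold and KRT15 4.12-fold, while SOX9 was 4.07-fold lower. Of 9215 genes 1087 lay at least 2-fold apart, 327 higher and 760 lower, where each GFP 18 h library against the other two gave 7, 1 and 14. Against 10000 random lists of matched expression, medians of NF-kB cytokines (log2 -1.21) and of mesenchymal and matrix genes (-1.02) lay at percentile 0. Those of the stress response (0.94), keratinocyte differentiation (0.82), ribosomal proteins (0.73) and oxidative phosphorylation (0.49) lay at percentile 100. These percentiles are no test. Random lists leave out the correlation between genes of a list, and a single library gives no measure of variation between cultures. This library had a rank correlation of level and gene length of -0.153, where the GFP 18 h libraries had -0.054, -0.054 and -0.139. The folds, list medians and percentiles above were not adjusted for this trend.

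More genes were detected in Krox20 libraries at the later times. With each library thinned to 20000000 counts, genes with at least 10 counts numbered 12279 ± 18.6 and 12513 ± 56.4 with GFP and Krox20 at 18 h (SD, n = 3). They numbered 12505 ± 48.6 and 14242 ± 13.5 at 42 h, 12665 ± 76.0 and 15179 ± 25.0 at 66 h, and 12275 in the uninfected library. Libraries of the 2 arms did not overlap at any time, and no test was made of these totals.

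**Figure D5:**
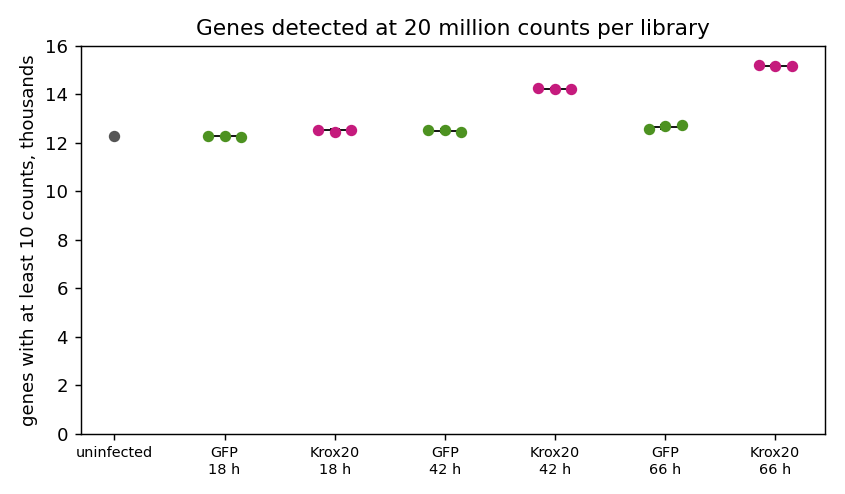
Genes with at least 10 counts in each library after thinning to 20000000 counts, by group, with points for libraries and bars for the mean and SD of 3. Krox20 libraries at 42 and 66 h lie at 14229 to 15203 genes, and all others at or below 12720.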

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

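The tests of depth, genomic DNA and HEK 293 RNA, of scaling for NOTCH1 and of a weaker effect in replicate 2, and the sorting of relabelings by whole arms, were chosen only after the results were seen, while the other splits and the tests of gene length were not. The effect of Krox20 differed between the 3 times for 9417 genes and between 18 and 66 h for 8028, each by an edgeR test of the difference itself. Of 194 genes named in the Krox20 comparisons, 159 differed between times. Opposite calls at 18 and 66 h, with a difference past the test, were found for 1095 genes, 479 lower then higher and 616 higher then lower. With library size alone these were 1257, 985 and 272, so the split between the 2 orders depends on scaling. Of the named genes 26 were among them. The chemokine genes CXCL8 (-4.38 and 2.70) and CCL20 (-1.64 and 3.44) and the mitotic genes NUSAP1 (-1.56 and 2.80) and CCNB1 (-1.30 and 2.36) were lower at 18 h and higher at 66 h. The stress response genes HERPUD1 (2.66 and -0.59) and PDIA4 (1.77 and -0.72) went the other way, and also with library size alone (2.54 and -0.31, 1.65 and -0.44). Of 50 random relabelings of the arms within each time, 1, the real one, gave as many genes for the test over times (9417, highest other 5730), and 1 for 18 against 66 h (8028, highest other 6892). These relabelings do not test the difference between times, because mixing the arms of a time also removes the Krox20 effect there: the 32 that mixed them at each time gave 0 genes, and 0 of the relabelings other than the real one kept whole arms at all 3 times.

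For single times there were too few splits for a share under 0.05. Of 10 splits of 6 libraries, 1 gave as many genes as the real split at 18 h (5338), 42 h (10880) and 66 h (11341), and in GFP cells from 18 to 42 h (4380) and from 18 to 66 h (8658). The highest other split gave 0 in each case. Every other split mixes the compared groups in both parts, so their difference enters the spread of that fit. These values of 0 therefore say nothing about chance.

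Genes with fewer than 3 counts summed over the GFP libraries and at least 10 in every Krox20 library numbered 72 of 6920 at 18 h, 646 of 6705 at 42 h and 1014 of 6434 at 66 h, and the reverse numbered 0 of 6335, 2 of 3930 and 1 of 3142. Greater depth as the whole cause is argued against, since at 18 h, where Krox20 libraries held 104.4% of the mean GFP depth, thinning to one depth left 59 genes (81.9%), and at 42 and 66 h Krox20 libraries were not deeper on average (98.9% and 86.8% of GFP). Genomic DNA is argued against, since 1.25% of 399 silent olfactory receptor genes were on at 66 h (95% interval 0.41 to 2.9) against 16.72% of 6035 others (15.79 to 17.68). RNA of the HEK 293 packaging cells that came in with the virus would be present by 18 h. Of the 1014 genes switched on at 66 h, 47 were switched on at 18 h. This argues against such RNA as the source of most of the 1014. Whether HEK 293 cells were carried over was not tested and stays open. At 66 h 9 of 14 genes of the HEK 293 list lay under the median switched-on gene (1.345 CPM). SOX11 (0.0272 CPM), LIN28B (0.0450), CDH2 (0.0703) and MYCN (0.113) lay far under it. NEFM (0.599 to 225 CPM from GFP to Krox20), NEFL (8.15 to 42.0), GAL (0.0508 to 4.13) and CRABP1 (0 to 4.16) were higher. That count of 9 cannot decide, since neither reading sets how many should lie under the median. That KROX20 itself may open the switched-on genes stays a hypothesis that was not tested.

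NOTCH1 was lower in Krox20 libraries at each time. A gene length trend as the whole cause is argued against, since with the trend of each library as a covariate the log2 fold change of NOTCH1 was -0.82 ± 0.06, -1.44 ± 0.06 and -1.43 ± 0.06 at 18, 42 and 66 h (SE, edgeR adjusted p = 2.0e-11, 2.2e-15 and 4.8e-16). The covariate came from the same counts, so these SE and adjusted p may be too small. In the main fit 24 genes matched on length, GC and level had median folds of 0.18, -0.06 and 0.23. Of these genes 4.2%, 8.3% and 8.3% lay below NOTCH1, so its fold was low but not outside their range. Scaling as the whole cause is argued against at 66 h, where library size alone gave NOTCH1 -1.12 (adjusted p = 0.0040), but at 42 h the call ended (-0.64, adjusted p = 0.069, from -0.93 ± 0.28) because the shift of all genes took up part of the fold. A biological candidate explanation, that KROX20 lowers NOTCH1, stays open as a hypothesis, and direct action was not tested.

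In Krox20 18 h replicate 2 EGR2 lay -1.60 on the log2 scale from the mean of the other two libraries. Of 25 genes matched to the human EGR2 gene on length, GC and level, 0% lay as low (lowest -0.90). They cannot decide whether the gene length trend of this library lowered EGR2. The length and GC of the carried sequence are not known. A weaker Krox20 effect in this library is argued against, since its deviation had a slope of 0.005 on the 42 h effect over 7359 genes. This slope was adjusted for gene length, GC and the mean deviation of the 3 GFP libraries that stand apart. Those 3 libraries, each adjusted for length, GC and the other 2, had 0.002, -0.004 and -0.023. The 18 h effect itself, which includes this library, had an unadjusted slope of 0.33, so that value is not on the same footing. Across genes its deviation correlated with the mean deviation of those 3 libraries (Pearson r = 0.93). Why EGR2 was low in this library stays open.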

How the results depend on the processing

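Leaving out the 4 libraries with another length trend, and the list test with no filter on low counts, were the only alternatives chosen after the data were seen. Without the 4 libraries 8253 genes were called at 18 h (5338 with all libraries, 5098 shared) and 7675 in GFP cells from 18 to 42 h (4380, 4248 shared), and the cause was not tested. Of the variance between replicates, 83.6% lay on the first axis, which followed gene length across genes (Spearman rho 0.71). Replicate pairs with 1 of the 4 libraries had chi-square per degree of freedom of 30.7 to 226, and other pairs 1.56 to 6.39. All groups share 1 estimate of the spread, so this axis enters each SE and adjusted p of the main fit. A 2-fold minimum by its construction left 1743, 5773 and 6539 genes at 18, 42 and 66 h, 4721 for the difference between 18 and 66 h, and 1154 and 4113 in GFP cells at 42 and 66 h. An estimated correlation left 10 list calls (3 upward, 7 downward) of 23 (9 and 14), and the cause was not tested, while no filter left 22 (8 and 14). Against GFP cells of 66 h, 2410 genes of the uninfected library lay 2-fold apart (1087 against 18 h). ATP5F1B, an ATP synthase gene, changed sign at 66 h with library size alone (0.006, adjusted p = 0.92, from -0.27), a move about as large as that of the median of all genes (0.015 to 0.288). With the length trend of each library, taken from the same counts, as a covariate, 9125, 12485 and 13401 genes were called at 18, 42 and 66 h. That is the fit used for NOTCH1. In the other alternatives counts stayed within 1.5 times, with leave-one-out ranges of 4271 to 5463 at 18 h, 10156 to 10443 at 42 h and 10854 to 12255 at 66 h. Of 430 values of named genes past the test, 402 kept direction and threshold in each alternative run for them and 28 lost the threshold in at least 1, where an adjusted p under 0.01 and a 2-fold minimum were applied to counts of genes only. Many of these genes were named for a small adjusted p or an extreme fold in the same data. Their share therefore does not carry over to called genes in general. By their deviations from the group mean, 2 of 18 libraries correlated best with their own replicate number. This cannot decide whether the numbers pair libraries. Most of that variance lay on the axis of gene length, and the 4 libraries that stand apart carry unlike numbers. A replicate block within each time gave 4087, 10036 and 10600 genes. Depth limits the floor, as genes with 0 control counts have folds known only as lower bounds.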

Other observations

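The genes in this part other than ACTC1, CST6, ELN and NPR1 were chosen after their values were seen, and no tests of them are given here. Several genes rose from the floor to abundant levels with Krox20. PEG10, a gene derived from a retrotransposon, was at 0.036 to 0.227 CPM over the GFP libraries and at 1.00 to 1.88, 251 to 277 and 561 to 629 CPM in Krox20 libraries at 18, 42 and 66 h. COL2A1, the cartilage collagen gene, was at 0.073 to 0.359 CPM with GFP and at 4.32 to 4.86, 392 to 395 and 332 to 369 with Krox20. At 66 h CST6, a cystatin gene, reached 286 ± 9.90 CPM (SD, n = 3), the elastin gene ELN 285 ± 16.8, NPR1 232 ± 10.4, the tensin gene TNS1 161 ± 16.1 and the parathyroid hormone receptor gene PTH1R 79.9 ± 1.76, each with 1 or 2 counts summed over the GFP libraries. FRG2 (214 ± 3.66) and FRG2C (61.5 ± 1.33) have near-identical copies and are uncertain.

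ACTC1, the cardiac actin gene, varied between replicates. It was at 14.6, 20.9 and 44.3 CPM in GFP 18 h libraries, 1.42, 2.39 and 36.3 in Krox20 18 h libraries, and 5.22, 40.7 and 0.036 in GFP 42 h libraries.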
